A study of Mus musculus with 6 samples.

How the data were processed

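Total RNA of 6 subcutaneous KLN205 tumours, 3 control and 3 anti-PD-1, was amplified and labelled with biotin from 250 ng per sample, per the labels' protocols, and read on Clariom S Mouse arrays. The deposited log2 values are signals per transcript cluster that the authors made with the SST-RMA gene-level method, per the file headers; as generally defined, this method corrects background and normalizes between arrays. The submitters' processing notes name the Transcriptome Analysis Console, and its version is not given in the sources used here. The annotation is for the mouse build mm10, per the file headers. The authors' deposited table also holds group averages in log2, a standard deviation per group, a call per group whether a cluster was expressed, a signed fold change (a score that is negative where control lies below anti-PD-1), and a p-value with its FDR, per the file headers. The rule behind the averages, the expressed calls and the test is not given in the sources used here. A second deposited table of log2 values held the same signals, and 0 values differed between the tables. No scanner files were used here, so background correction and between-array normalization could not be varied from the start. SST-RMA normalization holds the overall distribution of signals alike between arrays, so that the log2 differences are relative to the bulk of genes on the array and a change common to most genes would not appear.

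Samples were grouped by the treatment label of each sample, and columns were assigned to samples by the names in the sample titles. Of 22206 clusters, 836 with several gene names and 3 without one were left out of the gene tests. For the 132 genes with more than 1 cluster the cluster with the highest mean over all 6 arrays was kept, which left 21154 genes. No filter on dim signals was used. Symbols of the gene lists that the array names differently were looked up among the synonyms of a RefSeq gene table (GRCm38.p6), which was used for names only.

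Anti-PD-1 was compared with control by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A second threshold, unadjusted p under 0.05 and at least 2-fold, was applied without correction. A total of 41 gene lists of cell types and pathways was written before the data were examined and tested with camera at a correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An exact permutation test of 3 against 3 cannot give a two-sided p under 0.1, so no such test was run for single genes. Errors are standard deviations between the 3 arrays of a group or, marked SE for single genes, the standard error of the limma fit. For differences of list scores and of their residuals, the SE comes from the spread between arrays within each group. For the sets of mammary and neutrophil genes it comes from the spread over genes and does not measure that between tumours. Where the authors call a cluster not expressed in a group, its fold is given as a bound: the mean of the brighter group over the mean of the dimmer one, each dim value raised to the lowest signal of any cluster called expressed on that array if it lay below it. No value of the genes given such a bound in the text lay below that signal. Each bound therefore equals the fold of the group means and carries the same error. A list score per array is the median over the list's genes of the log2 signal minus the gene's mean over the 6 arrays.

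The rule for the genes named was fixed before the data were examined. It took the genes past the adjusted threshold whose groups did not overlap, filled up to 10 per direction by size with genes at unadjusted p under 0.05, at least 2-fold and without overlap. Up to 4 members of each called list and 2 of a list not called, by smallest p, and a set of checkpoint, T cell and proliferation genes could be named besides. Predicted genes were counted and not used for filling. Genes named outside the rule were chosen after their values were seen: the caseins, Krt1, Krt10 and Adipoq where single arrays are described, Tgfb3, Ski, Sox2, Retnlg, Ltf, Mmp9, Hdc, Hba-a1, Hba-a2 and those so marked in the text.

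The gene test was tried on simulated data with the spread of the real genes and 200 of 21154 genes changed. Values were drawn independently for each gene and with the same spread in both groups. In the real arrays the SD was over 1 log2 unit for 2260 genes in control and 380 in anti-PD-1 tumours. The simulated shares and false calls may therefore not hold for the real arrays. For 3 arrays against 3, 6.80% of genes changed by 1 log2 unit, 55.8% of those changed by 2, 79.6% of those changed by 3 and 88.6% of those changed by 4 passed the adjusted threshold, with 6.80 false calls per draw on average. With the spread of the arrays without control replicate 3 these shares were 21.0%, 72.8%, 91.4% and 94.4%, with as many false calls on average. For simulated lists of 20 unchanged genes, camera with the preset correlation gave p under 0.05 in 3.50% of lists when genes were independent, in 18.2% at a correlation of 0.1 and in 33.2% at a correlation of 0.3. With an estimated correlation these shares were 0.25%, 3.00% and 4.25%. The alternatives tried were quantile normalization and median centring of the deposited values, leaving out the 33.3% of genes with the lowest mean, eBayes with trend and robust settings, array weights, the second deposited table, the mean of a gene's clusters, leaving out each array, the replicate number as a block, other thresholds, and camera with an estimated correlation, fry and camera on ranks for the lists. Control replicate 4 alone as control, lists with clusters of several names, and the estimated correlation without control replicate 3 were added after the data had been seen.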

Results

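Gene expression was measured in subcutaneous tumours grown in mice from KLN205, a mouse squamous cell carcinoma line of the lung. Each inoculum held 1000000 cells in 50 µL of culture medium and 100 µL of the basement membrane gel Matrigel. The treatment protocol gives 250 µg of antibody into the peritoneum once per 3 days. Total RNA of 3 tumours given an antibody against PD-1, the inhibitory receptor of T cells, and of 3 control tumours was hybridised to Clariom S Mouse arrays, which read 1 sample per array. The sample labels name the controls as tumours without anti-PD-1, while the treatment protocol names an isotype antibody. The series text speaks of cells that survived 7 days after treatment, while the sample labels name tumour tissue, so the values were read as those of whole tumour pieces with their host cells. The labels number the tumours and do not say that each came from its own animal, so that p-values measure only the spread between these samples. Each array gave a log2 signal for 22206 transcript clusters, and the median signal per array lay between 7.04 and 7.13. The number of arrays, 3 per group, limits the precision of every comparison.

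Control replicate 3 stood apart from the other arrays. Its Pearson correlation with them, across genes, was between 0.907 and 0.936, while the other 5 arrays correlated with each other between 0.973 and 0.987. The first principal component, with 61.5% of the variance, set this array against the rest. It held the highest signals of fat genes, with Adipoq, the adipocyte hormone adiponectin, at 17.32 against 6.53 to 12.76 elsewhere. It also held the lowest signal of the basal keratin Krt5, at 11.00 against 13.14 to 18.15 elsewhere. Milk protein genes, which were singled out after their values were seen, were high in control replicates 2 and 3. Csn2 (beta-casein) read 13.68 and 16.21 there and between 5.13 and 5.85 in the other 4 arrays. The suprabasal skin keratins Krt1 and Krt10 were low in the same pair of arrays, with Krt1 at 5.17 and 3.98, against 14.12 to 16.33 in control replicate 4 and the anti-PD-1 tumours. Skeletal muscle genes were low in anti-PD-1 replicate 3, where Myh4, a fast myosin heavy chain, read 8.80 against 13.60 to 17.65 in the other arrays.

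**Figure D1:**
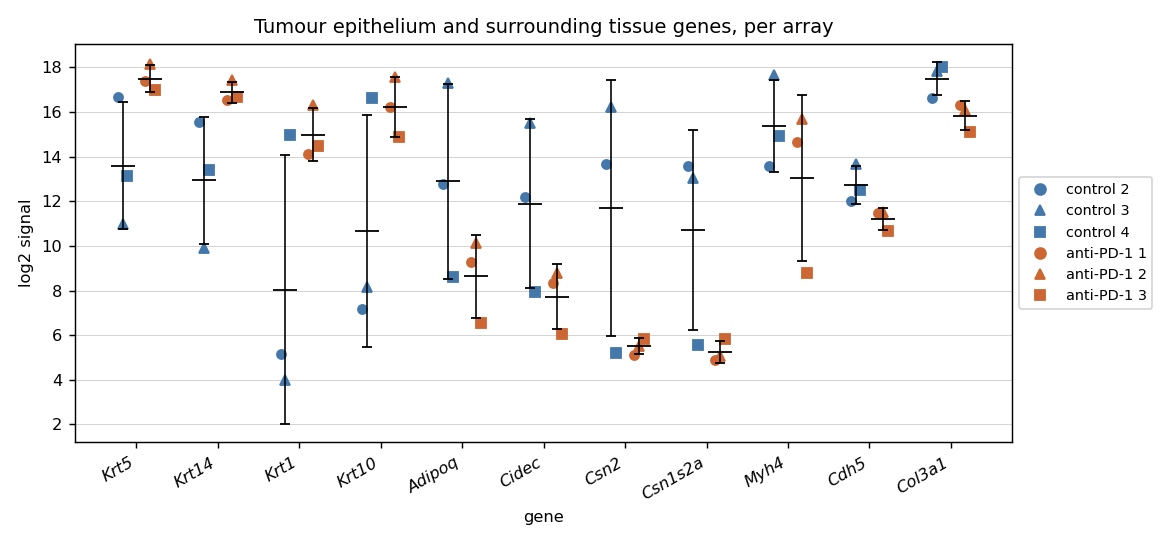
Log2 signal (vertical axis) of genes of squamous epithelium, fat, milk, muscle, vessel and matrix (horizontal axis) in each of the 3 control arrays (blue) and 3 anti-PD-1 arrays (orange), with marker shapes for the replicates and black bars for the group mean and SD. Adipoq reached 17.32 in control replicate 3, Csn2 read 13.68 and 16.21 in control replicates 2 and 3 and at most 5.85 elsewhere, and Krt5 was lowest, at 11.00, in control replicate 3.

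The comparison of anti-PD-1 with control tumours asked which genes differ in KLN205 tumours that persist under PD-1 blockade. Stefin A1 was the clearest difference. Stfa1, a cysteine protease inhibitor gene on chromosome 16 (mm10, 36277148 to 36285371), rose from 4.76 ± 0.22 in control to 9.13 ± 0.48 in anti-PD-1 tumours (log2 signal, mean ± SD, n = 3 each). Its log2 difference was 4.38 ± 0.29 (SE), anti-PD-1 minus control, with an adjusted p of 0.0411 by limma. The deposited calls list Stfa1 as not expressed in the controls, so the change reads as at least 20.8-fold by the group means. This bound was 17.1-fold without anti-PD-1 replicate 3. The direction used here is opposite to that of the authors' deposited table, which gives control over anti-PD-1.

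Of 21154 genes tested, Stfa1 alone passed the adjusted threshold, while 4 genes passed without control replicate 3, 3 without control replicate 4 and 0 by limma without each of the other arrays. Without correction for the number of genes, 2051 genes (9.70%) had p under 0.05, and 909 of these differed at least 2-fold, 453 higher and 456 lower in anti-PD-1 tumours. This count was 1928 without control replicate 2 and 567 without anti-PD-1 replicate 3. The groups did not overlap in 3506 genes (16.6%), where chance gives 10% on average over all splits of the arrays. Genes vary together, so that a single split can stray from 10%, and the difference from 10% was not tested. Stfa1 had an adjusted p of 0.108 without control replicate 2, 0.0540 without control replicate 4, 0.385 without anti-PD-1 replicate 1, 0.417 without anti-PD-1 replicate 2 and 0.120 without anti-PD-1 replicate 3. Over all alternatives its adjusted p ran from 0.0265 to 0.915, and its log2 difference stayed between 4.10 and 4.64.

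Among genes that did not pass the adjusted threshold, the largest non-overlapping differences upward included several genes of squamous epithelium. The rule filled this group with genes at unadjusted p under 0.05 and at least 2-fold. Gsdmc, a gasdermin gene on chromosome 15 (63775971 to 63808759), was higher by 6.23 ± 0.89 (SE) in log2 signal, from 4.31 ± 1.88 to 10.53 ± 0.57, or at least 74.9-fold, with an adjusted p of 0.386. This bound was 47.5-fold without control replicate 3 and 158-fold without control replicate 4. Krt16, a keratin of activated epidermis, was higher by 5.07, and the desmosomal cadherin Dsc3 by 4.99. Krt14 and Krt5, the keratin pair of basal squamous cells, were higher by 3.93 and 3.90. Calm4, Dmkn and Ly6d, all expressed in differentiating squamous epithelium, were higher by 4.68, 4.37 and 4.16, and Stfa3 by 4.24. Without control replicate 3 the differences were smaller, at 2.60 for Krt5, 2.41 for Krt14, 2.15 for Dmkn and 2.55 for Ly6d. For Calm4 and Dsc3 control replicate 4 read 11.42 and 11.18, close to the lowest anti-PD-1 values of 11.47 and 11.69, while control replicates 2 and 3 read between 5.42 and 6.10.

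The stefin A genes lie side by side and their copies are near-identical, as are those of the small proline-rich 2 genes, so that the signals of single members are uncertain. Of 10 stefin A family members measured, 9 were higher in anti-PD-1 tumours, with a median log2 difference of 1.99, and 7 of them had no overlap between groups. All 8 small proline-rich 2 members were higher, with a median of 1.28. Both counts were the same after quantile normalization and median centring, which had little room to change them, as the array medians already lay between 7.04 and 7.13. Both families were chosen after the leading genes had been seen. Clusters with several names are not in these counts. Of these, chosen after their values were seen, Sprr2a2 with Sprr2a1 differed by 6.60, Sprr2a3 with Sprr2a1 by 6.59 and BC100530 with Stfa3 by 5.43. Without control replicate 3 they differed by 4.545, 5.26 and 5.06. None passed the adjusted threshold.

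None of the largest non-overlapping differences downward passed the adjusted threshold. Retnla, a marker gene of alternatively activated macrophages on chromosome 16 (48842552 to 48844461), read 14.06 ± 2.96 in control and 7.79 ± 2.08 in anti-PD-1 tumours, a log2 difference of -6.27 ± 1.61 (SE) with an adjusted p of 0.506. Jchain, the joining chain of secreted antibodies, differed by -5.03 and Rnase2a by -4.45. Cyp2e1, Slc25a23, Abca8a, Osr1, Igfbp5 and Clec3b differed by between -4.33 and -3.59. Pigr, the receptor that carries polymeric antibodies across epithelia, was not called expressed in anti-PD-1 tumours and was at least 19.4-fold higher in control, with its highest signal, 11.58, in control replicate 4. The bound for Pigr was 6.64-fold without control replicate 4, 31.0-fold without control replicate 2 and 35.4-fold without control replicate 3. Several of these genes peaked in the array rich in fat genes, control replicate 3, where Retnla read 16.30 and Cyp2e1 13.43. Without that array the differences were -5.15 for Retnla, -2.52 for Cyp2e1, -2.02 for Slc25a23, -2.31 for Abca8a, -1.80 for Osr1 and -1.85 for Igfbp5.

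Genes of squamous epithelium, cell division and sugar metabolism shifted upward as groups in anti-PD-1 tumours by camera with a preset correlation. For each of these 7 lists the adjusted p = 0.573 with an estimated correlation. In the list of basal squamous genes 17 of 18 measured members were higher, with a median log2 difference of 2.23, and in that of cornified epithelium 23 of 26, with a median of 2.14. All 25 mitosis genes were higher, with a median of 1.32, and 24 of 25 DNA replication genes, with a median of 0.76. Of 17 glycolysis genes 16 were higher (median 0.90), of 22 hypoxia genes 18 (median 0.93), and all 20 ribosomal protein genes (median 0.57).

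The mitotic kinase gene Cdk1 was higher by 2.38, Cdc20, an activator of the anaphase-promoting complex, by 1.87, Top2a by 1.66 and Aurkb by 1.48. Cdt1 and E2f1, which act at the entry into DNA replication, were higher by 1.05 and 1.16. Ndrg1, a gene induced by low oxygen, was higher by 2.55 ± 0.75 (SE), and Ldha and Pfkl, enzymes of glycolysis, by 1.08 and 1.53. Sprr2d, a cornified envelope precursor, was higher by 3.56, and Sfn by 3.46. Cdh1, the epithelial cadherin, went the other way within the basal list and differed by -0.86. Without control replicate 3 the differences were smaller, at 1.42 for Cdk1, 1.29 for Cdc20, 1.00 for Top2a and 2.21 for Sfn. None of these members passed the adjusted threshold over all genes. Adjusted over the list alone, 1 cornified gene passed and no gene of the basal, mitosis, replication, glycolysis, hypoxia or ribosomal lists. Without control replicate 3 the basal count was 5, namely Sfn, Krt14, Perp and Sox2 upward and Cdh1 downward.

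With camera at a preset correlation of 0.01, 22 of 41 lists were called, 16 upward and 6 downward. The adjusted p was 2.13e-09 for mitosis, 9.06e-09 for cornified epithelium, 2.34e-08 for ribosomal proteins, 1.13e-07 for DNA replication and 2.93e-07 for basal squamous epithelium. It was 1.81e-05 for glycolysis and 0.000290 for hypoxia. With an estimated correlation no list was called, and the smallest adjusted p was 0.573. Without control replicate 3 the same 7 lists were called upward again at the preset correlation, with medians of 1.25 for basal squamous, 1.42 for cornified, 0.65 for mitosis, 0.43 for replication, 0.68 for glycolysis, 0.62 for hypoxia and 0.52 for ribosomal genes. The glycolysis median was 0.57 without control replicate 4. Of the 7 lists, only basal squamous epithelium had all 3 anti-PD-1 scores above all 3 control scores. Control replicate 2 lay above the lowest anti-PD-1 score for mitosis (0.55 against 0.51), replication (0.33 against 0.29), hypoxia (0.54 against 0.38), glycolysis (0.39 against 0.32) and ribosomal genes (0.015 against 0.005), and control replicate 4 did so for cornified epithelium (0.63 against 0.59). Smaller upward calls were those of hair follicle genes (17 of 19 higher, median 0.47), p53 targets (18 of 23, median 0.43) and oxidative phosphorylation (21 of 25, median 0.26). Their adjusted p = 0.573, 0.693 and 0.912 with an estimated correlation. The p53 call was lost without control replicate 3 (median 0.21, adjusted p = 0.113) and without anti-PD-1 replicate 2 (0.47, 0.0520), and its median was 0.74 without control replicate 2. The hair follicle call was lost without anti-PD-1 replicate 2 (median 0.063, adjusted p = 0.0989), and its median was 0.82 without anti-PD-1 replicate 3. The oxidative phosphorylation call was lost without control replicate 2 (median 0.26, adjusted p = 0.128), control replicate 4 (0.043, 0.989), anti-PD-1 replicate 1 (0.26, 0.103) and anti-PD-1 replicate 3 (0.17, 0.287), and its median was 0.43 without control replicate 3.

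**Figure D2:**
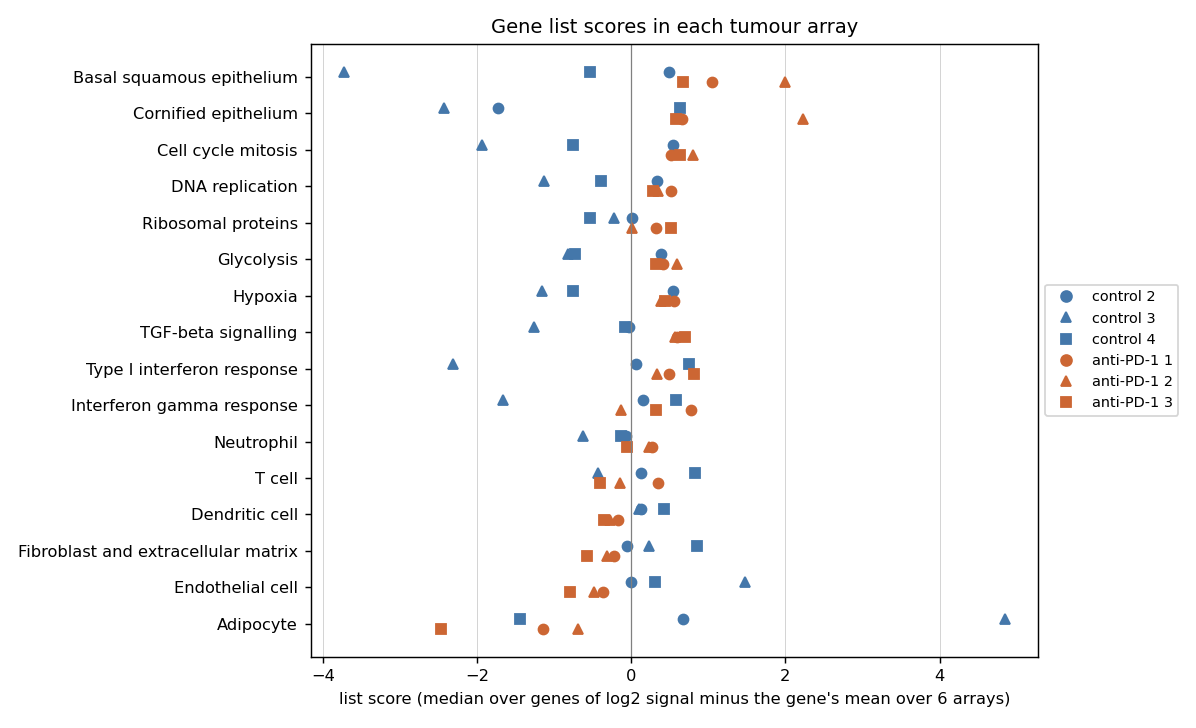
Scores of 16 gene lists (vertical axis) in each array, as the median over a list's genes of the log2 signal minus the gene's mean over the 6 arrays (horizontal axis); each point is 1 array, control in blue and anti-PD-1 in orange. Control replicate 3 lies lowest for basal squamous genes (-3.73) and highest for adipocyte genes (4.85), and the 3 anti-PD-1 scores of TGF-beta signalling (0.57 to 0.70) lie above the 3 control scores (-1.26 to -0.03).

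TGF-beta ligands and receptors were higher together in anti-PD-1 tumours, and all 3 anti-PD-1 values lay above all 3 control values for each gene named in this paragraph. Tgfb2 (chromosome 1, 186623186 to 186705992) went from 8.90 ± 0.29 to 10.61 ± 0.06, a log2 difference of 1.71 ± 0.22 (SE). Tgfb1 (chromosome 7, 25687002 to 25705077) went from 13.33 ± 0.63 to 14.90 ± 0.08, a difference of 1.57 ± 0.33. Tgfb3 was higher by 1.06, and the receptor genes Tgfbr1 and Tgfbr2 by 1.70 and 1.20. Thbs1, whose product thrombospondin 1 activates latent TGF-beta, was higher by 1.57.

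In the TGF-beta list 18 of 20 genes were higher, with a median of 1.12. Adjusted over the list alone, 7 genes passed, namely Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2 and Thbs1 upward and the inhibitor Ski downward, at -0.73, and none passed over all genes, where the adjusted p of Tgfb2 was 0.364. The list was called upward (camera adjusted p = 9.39e-07), and the adjusted p = 0.573 with an estimated correlation. Without control replicate 3 the median was 0.80, and 9 genes passed over the list alone. The list of epithelial-mesenchymal transition, which shares Tgfb1 and Tgfbr1, was called upward with 17 of 21 genes higher (median 0.57, camera adjusted p = 0.00178), and its adjusted p = 0.573 with an estimated correlation. Besides these, Cdh2 (N-cadherin) was higher by 0.57, while Sparc, a matrix glycoprotein, differed by -0.74.

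**Figure D3:**
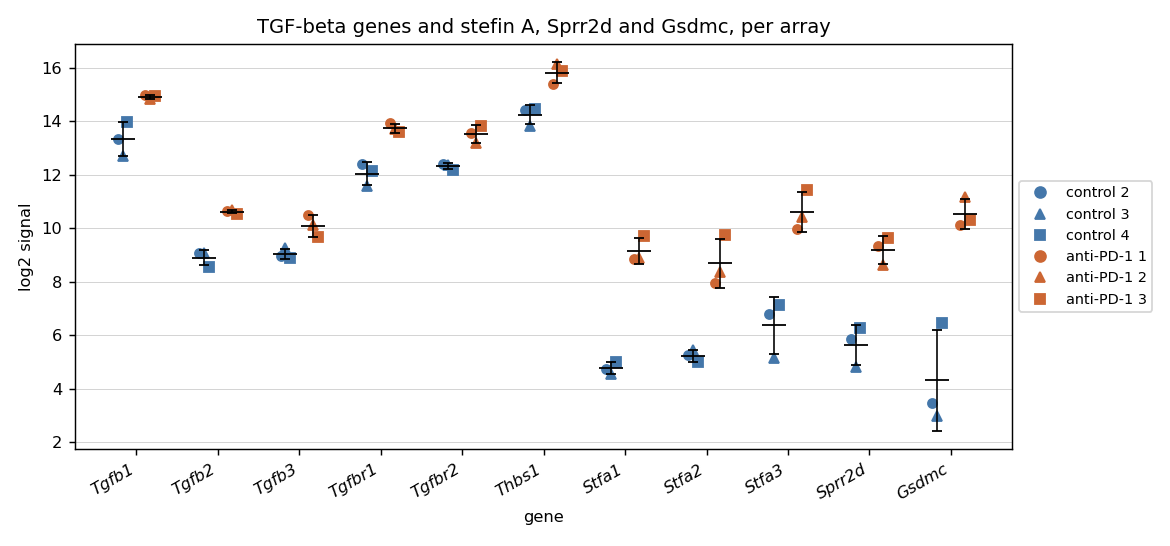
Log2 signal (vertical axis) of TGF-beta genes, stefin A genes, Sprr2d and Gsdmc (horizontal axis) in each control (blue) and anti-PD-1 (orange) array, with marker shapes for the replicates and black bars for the group mean and SD (n = 3). The groups did not overlap in any of these genes, and Stfa1 read 4.76 ± 0.22 in control and 9.13 ± 0.48 in anti-PD-1 tumours.

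Immune genes gave a mixed picture, with no difference in the drug target or the T cell markers that passed the test. Pdcd1, which encodes PD-1, read 6.02 ± 0.69 in control and 6.31 ± 0.63 in anti-PD-1 tumours, and Cd274, which encodes its ligand PD-L1, 10.37 ± 1.14 and 11.08 ± 0.22. The second ligand gene Pdcd1lg2 differed by -0.18 and Ctla4 by 0.06. Cd8a differed by -0.62 and Cd4 by -0.64. Ifng was higher by 0.37. Among cytotoxic genes, which were not called as a list (median 0.18, adjusted p = 0.240), Gzmb was higher by 1.63 and Gzma by 1.18, each short of the adjusted threshold. The cytotoxic list was called upward without control replicate 4 (median 0.40, adjusted p = 0.0178) and without anti-PD-1 replicate 2 (0.41, 0.0270), and its median was -0.24 without control replicate 3. Over all arrays its adjusted p = 0.912 with an estimated correlation. The cluster that names Foxp3 together with Ppp1r3fos differed by -0.35, and by -0.75 without control replicate 3. The proliferation marker Mki67 was higher by 0.62. Most of these values depended on single arrays. Without control replicate 3 the differences were -0.09 for Pdcd1, 0.08 for Cd274, -0.87 for Pdcd1lg2, -1.04 for Ctla4, -0.97 for Cd8a, 0.01 for Ifng, 0.92 for Gzmb and 0.27 for Mki67. Without control replicate 4 they were 1.21 for Cd274, 0.27 for Pdcd1lg2, 1.01 for Ctla4, -0.26 for Cd8a and -0.29 for Cd4, and without anti-PD-1 replicate 1 Ifng differed by -0.09. In the checkpoint list 16 of 23 genes were higher, but those with the smallest p, Tox and Vsir, differed by -1.43 and -1.06 without overlap between groups. With 1 array left out Tox stayed between -1.815 and -1.09 and Vsir between -1.31 and -0.90. In the T cell list 5 of 16 genes were higher, among them Bcl11b, with the smallest p, at 1.33 without overlap. Tox, Vsir and Bcl11b did not pass the adjusted threshold over all genes.

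Interferon and inflammatory lists were called upward, and each of these calls was lost without control replicate 3. Of 25 type I interferon genes 23 were higher (median 0.99), with Rsad2 and Oas1a higher by 1.58 and 1.62, and of 20 interferon gamma genes 18 (median 0.76), with Irgm1 higher by 1.62. The member with the smallest p went the other way in each list, Ifi27l2a at -1.23 and Ciita at -0.68. For the type I and the interferon gamma list the camera adjusted p was 0.000669 and 0.0251, and the adjusted p = 0.770 and 0.912 with an estimated correlation. Their medians were 0.25 and 0.03 without control replicate 3, where Rsad2, Oas1a and Irgm1 were higher by 0.48, 0.73 and 0.59. The type I interferon median was 1.57 without control replicate 4, and the interferon gamma call was also lost without anti-PD-1 replicate 1 (0.50, adjusted p = 0.261). Inflammatory cytokine genes had a median of 0.66 (20 of 25 higher, adjusted p = 0.0234), with the alarmin Il1a higher by 2.69 and the neutrophil chemokine Cxcl5 by 2.28, and the adjusted p = 0.756 with an estimated correlation. Their median was -0.10 without control replicate 3, with Il1a at 1.61, and 1.14 without control replicate 2 and 1.02 without control replicate 4. Without anti-PD-1 replicate 1 the call was lost as well (0.52, adjusted p = 0.114). Neutrophil genes had a median of 0.25 (14 of 20 higher, adjusted p = 0.0295), and the adjusted p = 0.573 with an estimated correlation. At unadjusted p under 0.05 by limma, 6 members were higher and 3 lower. S100a8 and S100a9, which keratinocytes express too, were higher by 2.21 and 1.45. Stfa2l1, Mmp9, Il1r2 and Hdc were higher by 1.84, 2.16, 1.23 and 1.23, while Lcn2, Retnlg and Ltf differed by -2.07, -2.14 and -1.51. Without control replicate 3 Ltf differed by -0.82 and Il1r2 by 0.73, and without control replicate 4 Lcn2 differed by -1.22. The neutrophil call was lost without control replicate 3 (median 0.20, adjusted p = 0.0773), control replicate 4 (0.33, 0.0723) and anti-PD-1 replicate 1 (0.26, 0.0775), and the median was 0.41 without control replicate 2 and 0.47 without anti-PD-1 replicate 3.

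Dendritic cell genes shifted downward, with 13 of 18 lower and a median of -0.48 (camera adjusted p = 0.00505), and the adjusted p = 0.573 with an estimated correlation. The homing receptor Ccr7 differed by -1.04, the cross-presenting cell marker Xcr1 by -0.96, the lectin Clec10a by -1.99 and the chemokine Ccl22 by -2.94. B and plasma cell genes were called downward as well (13 of 17 lower, median -0.33, adjusted p = 0.00298), and the adjusted p = 0.573 with an estimated correlation. The B and plasma cell call was lost without control replicate 3 (median -0.21, adjusted p = 0.0832), and the dendritic cell call was not (median -0.50). Without control replicate 4 the dendritic cell median was -0.31 and Ccl22 differed by -1.84. The T cell list (median -0.38, adjusted p = 0.222) and the macrophage list (median -0.15, adjusted p = 0.222) were not called over all arrays. After control replicate 3 was left out they were called downward, with medians of -0.57 and -0.52, as were the regulatory T cell (-0.48), checkpoint (-0.19) and MHC class II (-0.37) lists, whose medians over all arrays were 0.018, 0.22 and -0.13. These 5 calls held at the preset correlation only, and their adjusted p = 0.571 with an estimated correlation. The T cell and macrophage lists were also called downward without anti-PD-1 replicate 1 (medians -0.53 and -0.28). Other arrays moved these medians toward 0 or turned them. The T cell median was -0.089 (adjusted p = 0.627) without control replicate 4 and -0.20 (0.792) without anti-PD-1 replicate 3, and that of regulatory T cells was 0.28 and 0.18. The macrophage median was 0.012 without control replicate 4 and 0.083 without anti-PD-1 replicate 2, and that of MHC class II was 0.26 and 0.088.

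Genes of vessels, matrix and fat shifted downward in anti-PD-1 tumours by camera with a preset correlation. For all 3 lists the adjusted p = 0.573 with an estimated correlation. Of 19 endothelial genes 17 were lower, with a median of -1.04 (camera adjusted p = 1.13e-07), and the endothelial cadherin Cdh5, the receptor Tek and von Willebrand factor Vwf differed by -1.51, -2.53 and -1.26. Of 23 fibroblast and matrix genes 19 were lower, with a median of -0.74 (adjusted p = 2.72e-05). Mfap5 and Fap, a microfibril and an activated fibroblast gene, differed by -2.33 and -2.21 and passed over the list alone, and Col3a1 by -1.65, while Fbn1 was higher by 0.96. Of 20 adipocyte genes 19 were lower, with a median of -2.92 (adjusted p = 2.71e-06), and Lpl, the member with the smallest p, differed by -3.03. The adipocyte scores of control replicates 2 and 3 were 0.67 and 4.85, while control replicate 4 (-1.44) lay below anti-PD-1 replicates 1 (-1.14) and 2 (-0.70). The medians were -0.74 for endothelial, -0.80 for matrix and -1.09 for adipocyte genes when control replicate 3 was left out, and all 3 lists were called again. Lpl differed by -1.55 and Vwf by -0.84 there. Peripheral nerve genes were called downward (12 of 15 lower, median -0.27, adjusted p = 0.0180), and the adjusted p = 0.573 with an estimated correlation. That call was lost without control replicate 3 (adjusted p = 0.162), while the median was -0.30, and the median was -0.48 without anti-PD-1 replicate 1. Skeletal muscle genes were not called (median -0.73, adjusted p = 0.0728), nor were 10 measured red blood cell genes (median 0.07, and -0.036 without anti-PD-1 replicate 3), which held no haemoglobin gene. The 2 clusters that name both Hba-a1 and Hba-a2, alpha-globin genes, differed by -2.10 and -2.06, short of the adjusted threshold, and by -1.29 and -1.19 without control replicate 3. With such clusters kept in the list, the red blood cell median was -0.11 (adjusted p = 0.235). The muscle median was 0.059 without control replicate 3 and 0.50 without anti-PD-1 replicate 3, both not called. Without each of the other arrays the muscle list was called downward, with medians between -1.45 and -1.02, and over all arrays its adjusted p = 0.912 with an estimated correlation.

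The authors' deposited table gave 1 cluster at an FDR under 0.05, Stfa1, with an FDR of 0.0423. It lists 923 clusters at p under 0.05 and at least 2-fold, 498 higher in anti-PD-1 and 425 higher in control tumours. The group averages in the authors' deposited table are not arithmetic means, and 434 clusters had a control average that lay over 1 log2 unit from the mean of the 3 control signals. For 3296 of all clusters (14.8%) the direction in the authors' deposited table was opposite to that of the means, though for only 4 of the 923. For Krt1 the authors' deposited table gives a fold of -833.67, control over anti-PD-1, where the means differed 122-fold, with control signals of 5.17, 3.98 and 14.98.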

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

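The use of control replicate 4 alone, of lists with clusters of several names, and of an estimated correlation without control replicate 3 was chosen after the data were seen. The count of 1 gene past the adjusted threshold stayed at 1 with the dimmest genes left out, eBayes with trend and robust settings, array weights, the second table, the mean of clusters, an added 2-fold minimum and a threshold of 0.1. It was 0 by limma after quantile normalization (Stfa1 adjusted p = 0.0602) and after median centring (0.0532), with 908 and 930 genes at unadjusted p under 0.05 and 2-fold. Leaving out 1 array gave between 0 and 4 genes: 4 without control replicate 3, 3 without control replicate 4 and 0 without each of the others. With control replicate 4 alone as control, whose spread is then taken from the anti-PD-1 arrays, 11 genes passed. The 909 genes at unadjusted p and 2-fold became 1598 there, and between 567 (without anti-PD-1 replicate 3) and 1928 (without control replicate 2) when 1 array was left out. The 22 called lists became 18 to 23 under the other settings with camera at the preset correlation, 0 with an estimated correlation (1 list at unadjusted p under 0.05), 0 by fry (4 lists at unadjusted p under 0.05), and 0 without control replicate 3 with an estimated correlation. Of the 22 lists, 15 were called again in the same direction without control replicate 3 and 5 others were added. The replicate numbers 2 and 3 occur in both groups and the labels do not say that they pair tumours. Same-numbered arrays did not deviate together (r = -0.196 and -0.191, across genes), and with the number as a block 0 genes passed, 696 were at unadjusted p under 0.05 and 2-fold, and 22 lists were called. Some list directions turned. The checkpoint list, whose median was 0.22, had -0.19 without control replicate 3 and -0.34 with control replicate 4 alone, within a range of -0.19 to 0.40 when 1 array was left out. Interferon gamma genes had 0.026 and -0.24, with a downward test direction also at an estimated correlation, and ranged from 0.026 to 1.12 when 1 array was left out. Type I interferon genes had -0.27 with control replicate 4 alone, and oxidative phosphorylation genes 0.035 under the block, with a downward test direction. Of the 19 lists not called over all arrays, 16 had a median that changed sign when 1 array was left out, among them the cytotoxic list (-0.24 without control replicate 3) and the skeletal muscle list (0.059 without control replicate 3 and 0.50 without anti-PD-1 replicate 3). Of the called lists, 1 did so, that of inflammatory cytokines (-0.10 without control replicate 3). For these turns the cause was not tested, apart from the type I interferon list and control replicate 3. The design allows only 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. For genes past the adjusted threshold, 1 of the 10 splits, the real one, gave 1 gene and the highest other 0. For genes at unadjusted p and 2-fold, 1 of the 10 gave as many, 909 against 456 in the highest other. For lists, 2 of the 10 gave as many, 22 against 23 in the highest other.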

Other observations

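Of the 16 mast cell, basophil and eosinophil genes, 6 passed limma adjusted over the list alone and none over all genes. The list itself was not called, with a median of -0.20 (camera adjusted p = 0.200). The median was 0.13 without control replicate 3, -0.47 (camera adjusted p = 0.0517) without control replicate 2 and -0.40 (0.0888) without control replicate 4. The eosinophil genes Siglecf and Ccr3 differed by -1.54 and -2.30, anti-PD-1 minus control. Il5ra, which was not called expressed in anti-PD-1 tumours, was at least 2.83-fold higher in control by the group means, and 2.54-fold without anti-PD-1 replicate 2. The basophil and mast cell genes Mcpt8, Ms4a2 and Fcer1a were higher by 1.80, 1.12 and 0.66, while Kit, Prss34, Gata2, Tpsb2 and Cpa3 differed by -2.75, -0.46, -0.26, -0.14 and 0.007, none past the list threshold. In all 6 genes that passed the groups did not overlap, and all genes named here except Siglecf and Il5ra were chosen after their values were seen. With control replicate 3 left out, 7 genes of this list passed over the list alone, which adds Kit, at -1.03, and Gata2, Tpsb2 and Cpa3 were higher by 0.29, 0.65 and 1.13.

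Other genes passed the adjusted threshold when single arrays were left out. With control replicate 3 left out these were Ccl17, a dendritic cell chemokine, at -3.52, and Gm13304 and Gm10591, at 3.24 and 3.31, which the RefSeq table names as copies of the chemokine gene Ccl21 and which near-identical copies make uncertain. Without control replicate 4 they were Csn1s2a, a casein, at -8.06, Gsdmc at 7.30 and BC117090, of the stefin A family, at 3.97. Gapt, a gene of a GRB2-binding adaptor (-2.63 ± 0.29, SE) had the third smallest p over all arrays, with an adjusted p of 0.347, and was also named only after its value was seen.

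All tests in the following paragraphs were chosen after the result was seen, except that of the mammary genes. Fat and milk protein genes marked control replicates 2 and 3, and lists for squamous, dividing and interferon-responding cells were low in control replicate 3. Host tissue in control replicate 3 may account for the type I interferon shift, since the difference of list scores went from 1.05 over all arrays to 0.14 ± 0.37 (SE) without it. It stays open for the basal squamous list, at 1.27 ± 0.64 without that array, and for the mitosis list, at 0.76 ± 0.66, where the groups overlapped. For 10 mammary gland genes written down before their values were seen, control replicate 3 was set against the highest of the 4 arrays without milk protein signal. It lay above that array by a median of 0.025, and the SE of the mean over these genes was 0.59. This does not decide whether mammary tissue was the source. Cited1, Btn1a1, Folr1, Wap and Glycam1 stood 5.49, 1.58, 1.02, 0.38 and 0.21 above that highest array. Slc34a2, Pip, Csn1s2b, Lalba and Lao1 differed from it by -1.11, -0.42, -0.30, -0.17 and -0.16. An effect of the antibody on these lists remains open and was not tested apart from the group comparison.

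The score difference of the TGF-beta list went from 1.08 over all arrays to 0.68 ± 0.05 (SE) without control replicate 3, so host tissue in that array alone does not account for the difference in these samples. The control side of this SE rests on the scores of control replicates 2 and 4 only, -0.03 and -0.08, too few to tell the remaining difference from chance. A lower share of squamous tumour cells in the control pieces stays possible, because after removal of the linear relation to the basal squamous score the difference was 0.21 ± 0.20 over all arrays and 0.31 ± 0.19 without control replicate 3, with overlapping groups. That relation was fitted over both groups, which takes up part of any group difference. An effect of the antibody on these genes remains open and was not tested apart from the group comparison.

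The score difference of the stefin A and small proline-rich 2 genes was 1.62 ± 0.34 (SE) without control replicate 3 against 1.74 over all arrays, so that array alone does not account for them. More cornified skin in the anti-PD-1 pieces remains possible. Control replicate 4 had a cornified score of 0.63, in the anti-PD-1 range. Its family score lay 1.66 below the lowest anti-PD-1 family score, and the anti-PD-1 family scores spanned 0.63. This does not settle the question, as it is 1 array and the families were chosen after their leading genes had been seen. More neutrophils, which express stefin A genes as well, also remain possible. The 19 neutrophil genes other than stefins had a median difference of 0.24 ± 0.37 (SE over the genes) against 1.99 for the stefin A family. This SE does not measure the spread between tumours. Among the 19 genes S100a8 was higher and Retnlg, at -2.14, lower. A change within the tumour cells under the antibody was not tested apart from these.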
